A study of Homo sapiens with 2 samples.

How the data were processed

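RNA was extracted with Trizol from parental U87MG and radioresistant U87MG_F cells, and sequencing libraries were made with the Illumina TruSeq RNA Sample Prep Kit from total RNA, per the labels' protocols. CASAVA, TopHat and the genome build GRCh38 are named, without versions, per the submitters' processing notes. The quantification tool, the gene annotation, the use of strand and any filter are not given in the sources used here. The authors deposited 1 table of FPKM per gene with 1 column per library, given to 2 decimals, and each column was matched to its library by name. FPKM divide fragments by transcript length and by a library total, so they sum to a different value in each library, and a few abundant transcripts can shift all others.

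The table held 58439 identifiers, of which 57895 were found in GENCODE release 29 (GRCh38), the source of symbols, coordinates and exonic lengths. The other 544 included 206 with the prefix MSTRG, used for loci assembled from reads, and were not considered for naming. Exonic length was the union of a gene's annotated exons, which need not be the length the authors divided by. It can exceed the length of the transcripts expressed, so matching on it may leave part of a length bias. Exons shared by named genes with other expressed genes were looked up in this annotation. Beside those stated with the results, ACADVL, ACTA2, ATP5MF, ATP5MG, CCND1, COA1, HILPDA, HK2, MPG, NDUFA11, NDUFA13, PSMB10, RPS3A, TAGLN, TPI1 and VIM share exons with an expressed gene, and their values could include its fragments. A total of 36318 identifiers were at 0 in both libraries.

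The comparison was radioresistant against parental, with 1 library in each group. It was expressed as log2((FPKM + 1)/(FPKM + 1)), with a pseudocount of 1, for 12757 genes with a mean FPKM of at least 1. A fold on this scale understates the difference for low genes. No test across samples was possible, so genes were counted by size (at least 2-fold). For each of 48 gene lists the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when its percentile lay outside the middle 95% (below 2.5 or above 97.5), and lists needed at least 3 measured members. Members were counted as higher or lower at 1.5-fold from the median gene. The lists, thresholds, alternative settings and naming rule were fixed before the data were examined. That rule takes, among genes with a mean FPKM of at least 5 and a symbol that is not clone-based, the 14 highest and 14 lowest ratios. It adds up to 4 members per list with the largest absolute ratios, all 7 mitochondrial-encoded complex I subunits, and identity genes including VIM, NES, GFAP and CDKN2A; a further identity gene is not reported here.

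Depth was estimated from the low values of genes with 1 transcript, 500 to 1200 bp long, with an FPKM under 0.8. A search over library totals and fragment lengths asked how often the values were whole numbers of fragments within 0.15. It gave 29.2 M fragments and a fragment length of 270.0 bp for the parental library, with 88.0% of 1350 values whole, and 23.4 M fragments and 280.0 bp for the radioresistant library, with 89.1% of 997 whole, where chance gives 30.0%. The totals are estimates of the authors' normalising total, not stated values.

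Alternatives chosen in advance were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, scaling to a median ratio of 0, rescaling to TPM with and without mitochondrial-encoded genes, quantile normalization, random lists from all genes, and thresholds of 1.5-fold and 4-fold. After a trend with gene length was seen, random lists matched on expression and length (10 by 10 bins), removal of length, GC content and abundance trends with polynomials of degree 3, and a count of protein-coding genes only were added. Length was known for 98.3% of genes past the filter.

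The list procedure was tested on simulated data for this comparison, with the length trend of 12538 real genes and a log2 shift of 0.4 planted in 5 lists in each of 10 simulations. Shifts were planted only in lists with at least 15 measured members, so recovery of smaller lists was not tested. Expression matching recovered 84.0% of 50 planted lists and called 7.00% of 357 unplanted ones. Matching on length recovered 88.0% and called 3.08%, and removing the trends recovered 88.0% and called 4.20%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.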

Results

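Gene expression was measured by RNA sequencing in U87MG, a human glioblastoma cell line, and in U87MG_F, a radioresistant population derived from it. U87MG_F had received 5 fractions of 2 Gy X-rays, a total of 10 Gy over 1 month, while the parental cells were passaged in parallel without irradiation. Each population was represented by 1 library, so no difference below has a replicate check, no p-value is given, and every comparison describes these 2 libraries. The values were FPKM (fragments normalised by transcript length and library total), which summed to 735797 in the parental and 917900 in the radioresistant library. The deposited FPKM carry no read totals, but whole-fragment steps among low values corresponded to about 29.2 M and 23.4 M normalising fragments. At that depth a transcript of 2 kb at an FPKM of 5 held 253 fragments in the parental and 201 in the radioresistant library. The 95% Poisson intervals were 88.1% to 113% and 86.5% to 115% of the value, and 3 fragments on such a transcript corresponded to an FPKM of 0.0593 and 0.0745. These intervals and floors cover counting error only.

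The study addressed whether radioresistant glioma cells depend on mitochondrial complex I. Across 12757 genes with a mean FPKM of at least 1, 389 were at least 2-fold higher in the radioresistant library and 1036 at least 2-fold lower, on the log2(FPKM + 1) scale. The genes with the lowest ratios included EGR1, a growth factor-induced transcription factor (chromosome 5, 138465490 to 138469315, GRCh38), at 152 FPKM in parental and 7.37 in radioresistant cells. The cytokine IL1B (chromosome 2, 112829751 to 112836903) stood at 164 and 12.9, the colony-stimulating factor CSF3 at 375 and 58.0, and the de novo DNA methyltransferase DNMT3B at 13.7 and 1.17. At the other end were the axonemal dynein DNAH3 (chromosome 16, 20933111 to 21159441), at 0.03 and 32.1, the semaphorin SEMA6D at 0.49 and 42.4, and the kinase-like gene RPS6KC1 at 1.61 and 23.2. The median log2 ratio of all genes past the filter was -0.14, and -0.43 when each library was rescaled to TPM, in which libraries share one total. Because of this offset, members of gene groups are counted below relative to the median of all genes. List medians below are as deposited unless stated and are lower on the TPM scale, such as 0.05 for fatty acid oxidation and -0.04 for base excision repair. The split of calls followed the scaling, with 27.3% of calls higher as deposited, 47.0% after setting the median ratio to 0, 46.0% after quantile normalization, and 8.92% after rescaling to TPM.

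Of the other genes named by size, the lower ones were USP41 (62.9 and 6.56 FPKM), KLHL3 (12.4 and 0.71), GPR157 (14.2 and 1.31), DNAJB14 (17.8 and 2.18) and the osmotic stress factor NFAT5 (10.0 and 1.28). The higher ones were the mitochondrial release factor MTRF1 (4.99 and 37.9), the neuromedin B receptor NMBR (0.80 and 9.84), the histone gene HIST1H4J (2.16 and 17.5), LINC02129 (0.24 and 33.1), DLGAP1-AS1 (5.00 and 33.4) and the pseudogene TECRP1 (1.20 and 11.8). Small non-coding RNAs were among them, with RN7SK at 6.70 and 50.7, RMRP at 2.33 and 20.8, and SNORA74B listed at 0 and at 14.5. SGO1-AS1 (26.8) and the pseudogene PSMC1P5 (16.3) were listed at 0 in the radioresistant library. Several of these values are uncertain because exons are shared with another expressed gene and the use of strand in counting is not given in the sources used here. They are SGO1-AS1, STX18-AS1 (18.5 and 1.34), EML5 (0.43 and 11.99) and PCBP1-AS1 (6.68 and 40.6), which overlap genes on the opposite strand. On the same strand, PIK3R2 (17.6 and 0.05), NFAT5 and the readthrough gene HNRNPUL2-BSCL2 (24.9 and 4.35) overlap other annotated genes.

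Complex I, the NADH dehydrogenase of the respiratory chain, split by genome of origin. All 37 nuclear-encoded subunits were measured and had a median log2 ratio of 0.55, and 25 of them were at least 1.5-fold higher than the median gene, with none 1.5-fold lower. NDUFB1 (chromosome 14, 92116122 to 92121917) stood at 182 FPKM in parental and 418 in radioresistant cells, NDUFA11 at 407 and 906, NDUFA13 at 285 and 622, and NDUFB7 at 314 and 653. The 19 assembly factors had a median of 0.44, with NDUFAF2 at 40.8 and 99.6, NDUFAF5 at 3.57 and 8.57, and COA1 at 41.7 and 84.4. The 7 mitochondrial-encoded subunits had a median of -1.31. MT-ND5 (mitochondrial genome, 12337 to 14148) stood at 267 and 79.5, MT-ND4 at 1692 and 633, MT-ND4L at 2549 and 1024, MT-ND6 at 240 and 93.4, MT-ND2 at 766 and 412, and MT-ND1 at 756 and 425. MT-ND3, at 1429 and 1614, was the exception, and it lay below the median gene after quantile normalization (-0.28). MT-ND3 (346 bp) and MT-ND4L (297 bp) are little longer than the fitted fragments of 270 and 280 bp. Their FPKM, and the direction of MT-ND3, may therefore depend on the effective length used. MT-ND4 and MT-ND4L share exonic sequence, so their fragments may not be separable, and they are not independent members. MT-ND6 lies beside MT-ND5 on the opposite strand, and the use of strand is not given, so its value may include fragments from MT-ND5.

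The nuclear subunits lay at percentile 99.85 of 10000 random lists of the same size matched on expression, and at 96.7, inside the middle 95%, when gene length was matched as well. The assembly factors lay at 99.99 and 99.8, and the mitochondrial-encoded subunits lay below all random lists under both matchings. After rescaling to TPM the medians were 0.23 for the nuclear subunits, 0.13 for the assembly factors and -1.63 for the mitochondrial-encoded subunits, against -0.43 for all genes. With trends removed the nuclear subunits went from 0.69 above the median of all genes to 0.25 above it. These percentiles are a description of these libraries.

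**Figure D1:**
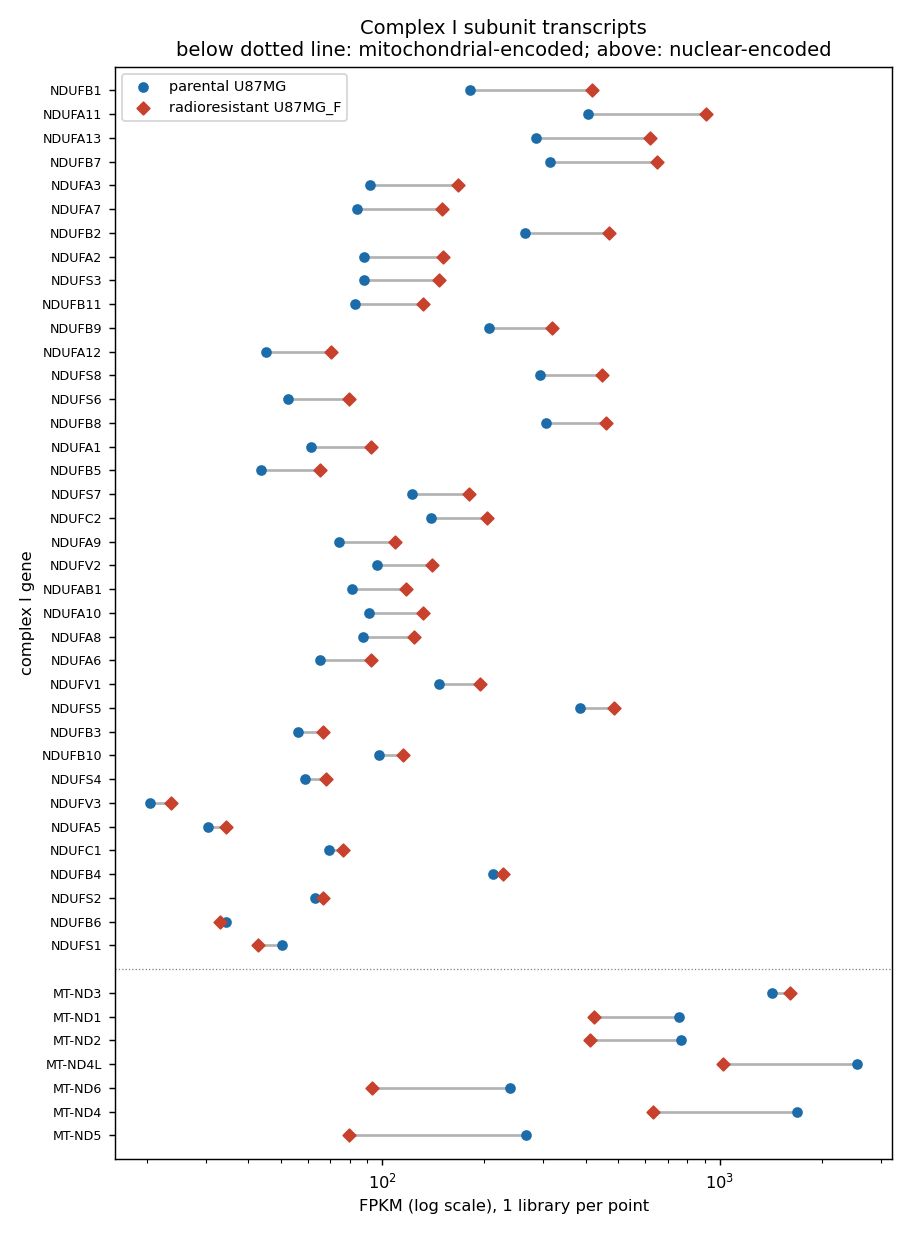
FPKM (log axis) of the 37 nuclear-encoded and 7 mitochondrial-encoded complex I subunits in parental U87MG (blue circles) and radioresistant U87MG_F (red diamonds), 1 library per point. Most nuclear subunits sit to the right in U87MG_F (median log2 ratio 0.55) and 6 of the mitochondrial-encoded ones to the left (median -1.31 over all 7), with MT-ND3 at 1429 and 1614 FPKM below the median gene after quantile normalization.

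For the other respiratory complexes the lists of nuclear genes had medians above that of all genes, and most of the mitochondrial-encoded subunits were lower. The nuclear lists also hold associated genes, such as COX7A2L, CYCS and ATP5IF1, and that of complex II includes assembly factors. The nuclear complex IV list had a median log2 ratio of 0.57 over 12 genes (COX7A2L 91.1 and 230.0 FPKM, COX5B 237 and 543), and that of complex V 0.59 over 18 genes (ATP5MF 776.8 and 1563, ATP5MG 35.3 and 71.5). Complex II (0.30, 8 genes, SDHC 115 and 197) and complex III (0.29, 10 genes, UQCRQ 201 and 430) were higher by less, and after rescaling to TPM their medians were -0.0084 and -0.024 against -0.43 for all genes. As deposited none of these 4 groups stood apart from expression-matched lists, at percentiles 93.6 for IV, 96.2 for V, 92.8 for II and 49.3 for III, but complex IV did after quantile normalization (98.3) and complex V without the filter (97.9), and III, IV and V did against lists drawn from all genes (97.99, 99.98 and 100). The 6 mitochondrial-encoded subunits of complexes III to V had a median of -0.88 and lay below all expression-matched lists (length-matched percentile 0.02), with MT-ATP6 at 1374 and 605, MT-ATP8 at 4832 and 2201, MT-CYB at 538 and 264, and MT-CO1 at 1943 and 1162. MT-CO2, at 3120 and 2441, was lower by less, and MT-CO3, at 2748 and 2541, lay above the median gene. MT-ATP6 shares sequence with MT-ATP8 and MT-CO3, so their fragments may not be separable. MT-ATP8, at 207 bp, is shorter than the fitted fragments, so its FPKM is uncertain. Over all 13 mitochondrial protein-coding genes, called mitochondrial mRNAs here, the median was -1.02, and 11 lay below the median gene. Because some share sequence, they are not 13 independent members. The mitochondrial share of the FPKM sum was 3.16% in parental and 1.61% in radioresistant cells. Mitochondrial ribosomal proteins were higher as a group (0.49, 54 genes, percentile 100, length-matched 99.6), with 32 of them at least 1.5-fold above the median gene, including MRPL17 at 81.4 and 157 and MRPS15 at 115 and 221. With trends removed their median went from 0.63 above that of all genes to 0.29 above it (percentile 99.99). Fatty acid oxidation genes were higher too (0.36, 17 genes, percentile 98.9, length-matched 99.5, and 96.4, inside the middle 95%, after quantile normalization), among them ECI1 at 9.32 and 20.3 and ACADVL at 166 and 281. Neither the tricarboxylic acid cycle (-0.07, 19 genes, percentile 25.5) nor mitochondrial biogenesis and dynamics (-0.23, 18 genes, percentile 24.1) stood apart, and both medians switched sides of the median gene after quantile normalization.

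Antioxidant and NRF2 target genes were higher as a group, with a median log2 ratio of 0.53 over 27 genes, 18 of them at least 1.5-fold above the median gene and none as far below. NQO1, a quinone reductase and classical NRF2 target (chromosome 16, 69706996 to 69726951), stood at 487 and 1435 FPKM, the peroxiredoxin PRDX5 at 263 and 575, and the lipid peroxide reductase GPX4 at 480 and 943. Ratios of 5 members were below 0, among them SLC7A11 at 4.99 and 3.37 and GCLC at 15.2 and 12.8. The group lay at percentile 99.6, and at 99.4 with length matched, where random lists had a median of 0.26. With trends removed its median went from 0.68 above that of all genes to 0.33 above it (percentile 99.9). Within the list ratios fell with length (Spearman correlation -0.59). Glycolysis and lactate genes went both ways, with HK2 at 67.3 and 28.2, PFKFB3 at 84.9 and 44.8, and TPI1 at 2498 and 4156. Their median of -0.02 over 24 genes was above the median gene, and below it after quantile normalization (-0.22), yet low for genes of their abundance (percentile 0.65, length-matched 9.93). Hypoxia response genes behaved alike (-0.08, 22 genes, percentile 1.55, length-matched 6.95, and below the median gene after quantile normalization at -0.20), with VEGFA at 454 and 187 and HILPDA at 149 and 280, of which VEGFA overlaps AL136131.3 on the opposite strand (62.6 and 106). Both groups had medians near 0 with members on either side, so their low percentiles rest on the abundance matching.

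Growth factor-induced and inflammatory transcripts were lower in the radioresistant cells. Immediate early genes had a median log2 ratio of -1.08 over 22 genes, 16 of them at least 1.5-fold below the median gene and none as far above, with FOS at 8.55 and 0.62 FPKM, the ERK pathway feedback gene SPRY4 at 8.47 and 1.21, and EGR2 at 20.3 and 4.40. NF-kB targets and secreted inflammatory factors had a median of -0.83 over 21 genes, 11 lower and 1 higher by that measure. Besides IL1B and CSF3, PTGS2, the inducible cyclooxygenase, stood at 9.42 and 1.30, and TNFAIP3, a feedback inhibitor of NF-kB, at 15.9 and 4.57. Both lists lay below all random lists, with or without length matching. Interferon-stimulated genes did not stand apart (0.03, 28 genes, percentile 96.8, but 99.4 without the filter), with IFIT3 at 4.33 and 8.28 and OAS3 at 6.39 and 3.77. Antigen presentation genes (0.11, 16 genes, percentile 60.7, below the median gene after quantile normalization at -0.28) held the immunoproteasome subunit PSMB10 at 52.1 and 118 and the peptidase ERAP2 at 9.34 and 2.85.

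Matrix and adhesion-related groups were lower. Extracellular matrix genes had a median log2 ratio of -0.71 over 25 genes, 12 at least 1.5-fold below the median gene and 2 above, with VCAN at 16.3 and 3.41 FPKM, LAMB1, which overlaps DLD on the opposite strand (74.96 and 52.6), at 54.2 and 13.7, and COL12A1 at 10.9 and 2.25. YAP/TEAD targets had a median of -0.96, with all 12 below the median gene as deposited, including TEAD1 at 15.6 and 5.09. Matrix proteases and inhibitors (-0.51, 13 genes) included MMP9 at 10.6 and 3.10 and TIMP4 at 14.4 and 28.5. TGF-beta targets (-0.37, 18 genes) contained CTGF at 20.5 and 7.88, while the contractile genes TAGLN, at 152 and 386, and ACTA2, at 167 and 414, were higher. Epithelial-mesenchymal regulators (-0.60, 11 genes) included ZEB1 at 5.44 and 1.40. All 5 groups stood apart with length matched, at percentiles 0.01 for matrix, 0 for YAP/TEAD, 0.01 for proteases, 0.89 for TGF-beta and 0.15 for epithelial-mesenchymal regulators. Against random lists drawn from all genes, TGF-beta targets (8.64) and matrix proteases (3.80) did not stand apart.

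**Figure D2:**
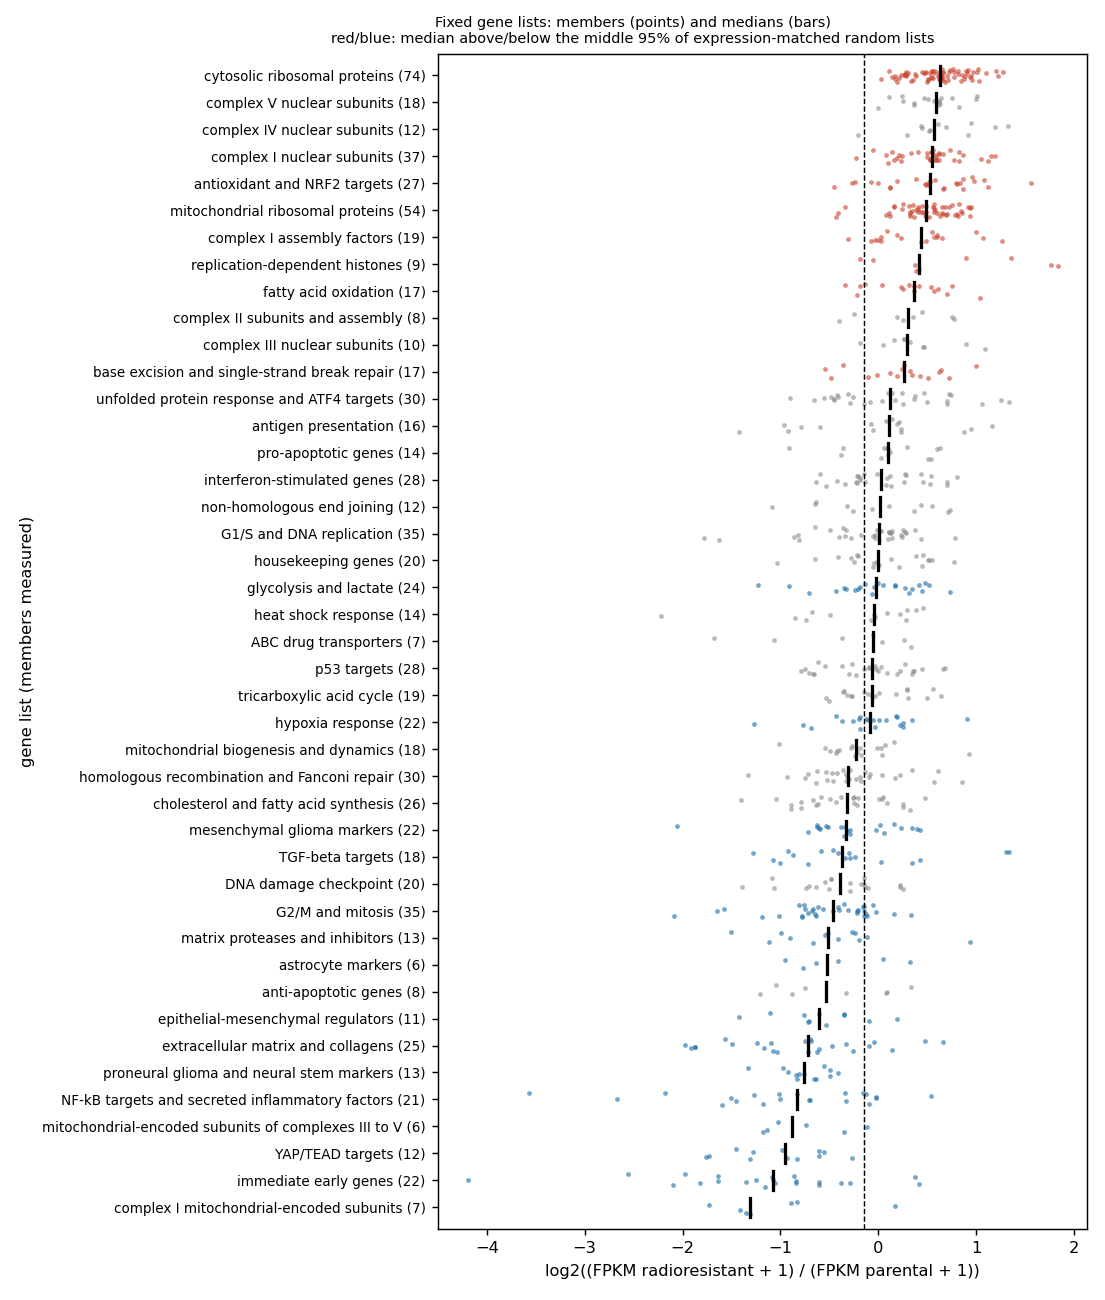
Log2 ratio of FPKM + 1, radioresistant over parental, for members (points) of the 43 lists with at least 6 measured genes, with list medians (bars) and the median of all genes (dashed line, -0.14). Red lists lie above and blue lists below the middle 95% of expression-matched random lists; immediate early genes (-1.08) and complex I mitochondrial-encoded subunits (-1.31) have the lowest medians shown.

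Mitotic transcripts were lower as a group while DNA replication transcripts were not. G2/M and mitosis genes had a median log2 ratio of -0.46 over 35 genes, 10 of them at least 1.5-fold below the median gene and none as far above, with the proliferation marker MKI67 (chromosome 10, 128096659 to 128126385) at 35.9 and 7.66 FPKM, ASPM at 7.59 and 1.74, and CENPF at 27.7 and 8.65. These 3 are the longest genes of the list, within which ratios fell with length (Spearman correlation -0.54). Another 25 members lay within 1.5-fold of the median gene, among them CCNB1 at 113 and 101 and AURKA at 53.3 and 52.3, and 7 lay above it. The list lay at percentile 0.01 and, length-matched, below all random lists. G1/S and DNA replication genes had a median of 0.01 (35 genes, percentile 51.3, below the median gene after quantile normalization), though UHRF1 stood at 66.2 and 18.6 and CCND1, cyclin D1, at 146 and 46.5. Base excision and single-strand break repair was higher (0.26, 17 genes, percentile 98.5, but 96.7, inside the middle 95%, with length matched), with the glycosylase MPG at 26.3 and 53.8. Homologous recombination and Fanconi repair (-0.31, 30 genes, percentile 29.2), non-homologous end joining (0.02, 12 genes, percentile 72.6) and the DNA damage checkpoint (-0.39, 20 genes, percentile 14.1) did not stand apart. At 1.5-fold from the median gene, 3 homologous recombination and Fanconi members were higher and 3 lower. For end joining 3 were higher and 1 lower, and for the checkpoint none were higher and 4 lower. Among those lower were RAD50 at 6.61 and 2.02, PRKDC, the DNA-dependent protein kinase, at 84.5 and 39.4, and CLSPN at 15.9 and 5.43. RAD51B, at 5.61 and 10.97, was among those higher. Targets of p53 did not stand apart (-0.06, 28 genes, percentile 72.4), with MDM2 at 13.3 and 7.28 and TRIAP1 at 20.3 and 33.2. Anti-apoptotic genes had a median of -0.53 over 8 genes (percentile 2.72, and outside the middle 95% with length matched at 2.26 and after rescaling to TPM at 2.47), with MCL1 at 102 and 60.4. Pro-apoptotic genes had a median of 0.10 over 14 genes (percentile 89.5, and 97.6 after quantile normalization). Of these, 4 were at least 1.5-fold above the median gene and 1 as far below, and BCL2L11, at 2.90 and 1.08, was lower. Exons of MDM2 overlap AC025423.2 on the same strand (18.5 and listed at 0), and those of BCL2L11 overlap MIR4435-2HG on the opposite strand, so both values are uncertain.

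Glioma and neural marker lists had medians below that of all genes as deposited. Proneural glioma and neural stem markers had a median log2 ratio of -0.76, with all 13 measured members below the median gene as deposited, including NCAM1 at 9.34 and 3.12 FPKM, ID1 at 231 and 122, and MYC at 76.2 and 42.1 (percentile 0.18, length-matched 0.32). The other 16 of its 29 members were below the filter, 5 of them at 0 in both libraries. Mesenchymal glioma markers had a median of -0.33 over 22 genes (percentile 0.18, length-matched 0.28, and 11.6 against lists drawn from all genes, where they no longer stood apart). Of these, 21 lay within 1.5-fold of the median gene and 8 lay above it. RUNX1, at 15.9 and 3.06, was the only one farther below. Astrocyte markers had a median of -0.53 over 6 genes (percentile 2.14, length-matched 2.93), with CLU at 62.6 and 31.8, and did not stand apart without the filter (9.80), after quantile normalization (3.98) or against lists drawn from all genes (8.28) either. Neuron (-0.31, 4 genes, percentile 31.5), oligodendrocyte lineage (-0.56, 3 genes, percentile 14.01) and myeloid and lymphoid markers (0.01, 3 genes, percentile 53.5) did not stand apart. Endothelial and epithelial markers had too few measured members for a percentile, with KDR at 5.18 and 1.67, KRT8 at 9.99 and 11.6, and MUC1 at 4.32 and 4.17. Among the identity genes, VIM stood at 2960.3 and 2322, NES at 2.37 and 1.40, and GFAP at 1.01 and 1.52, and CDKN2A was listed at 0 in both libraries. GFAP is uncertain, since its exons overlap CCDC103 (2.46 and 5.40) and FAM187A (4.43 and 3.41) on the opposite strand.

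Cytosolic ribosomal protein genes were above the median gene in all 74 cases as deposited (median log2 ratio 0.63), with RPS3A at 1749 and 4233 FPKM and RPL35 at 3065 and 7073. They lay at percentile 99.96, length-matched 100, and inside the middle 95% after quantile normalization (88.9) or removal of trends (91.2). Replication-dependent histones were higher (0.42, 9 genes, percentile 99.6, but 87.4 length-matched and 94.97 with trends removed, inside the middle 95%), with HIST1H1C at 8.09 and 22.2. Unfolded protein response and ATF4 targets did not stand apart (0.12, 30 genes, percentile 47.1), and its members with log2 ratios farthest from 0 were ASNS at 108 and 273, PSAT1 at 115 and 277, MTHFD2 at 83.6 and 175, and SEL1L at 34.5 and 18.0. Cholesterol and fatty acid synthesis (-0.32, 26 genes, percentile 3.69, and 1.60 at a mean FPKM of at least 5) included FASN at 30.3 and 14.2. The heat shock response (-0.04, 14 genes, percentile 12.02, below the median gene after quantile normalization, and percentile 1.15 with trends removed) included HSPA6 at 4.42 and 0.16. ABC drug transporters (-0.05, 7 genes, percentile 81.7, length-matched 97.6, and 98.2 with trends removed) included ABCA1 at 7.76 and 1.73. Housekeeping genes had a median of 0.00 over 20 genes (percentile 4.54, below the median gene after quantile normalization), with POLR2A at 32.2 and 15.2 and RPLP0 at 3476 and 5098. Over the 46 lists with at least 3 measured genes, 23 stood apart, 15 low and 8 high. The nominal expectation is 2.3, and the rate of false calls in simulated data with the length trend gives 3.22. Of the lists that stood apart, 17 did so with length matched too.

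Log2 ratios were lower for longer genes. Across 12538 genes with a known exonic length the Spearman correlation of ratio with length was -0.40, and -0.44 among 11218 protein-coding genes; genes are not independent replicates. The shortest decile of genes, with a median length of 992 bp, had a median log2 ratio of 0.26, and the longest decile, with a median length of 12694 bp, one of -0.62. This is why length-matched percentiles stand beside many of the gene groups above. The groups given without one did not stand apart with length matched either. The nuclear complex I genes had a median exonic length of 2263 bp, in the second decile. Such lengths join all annotated exons of a gene (9851 bp for NDUFA5, 4839 bp for NDUFA11) and can exceed the transcripts expressed. Matching on them may therefore correct for length only in part.

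**Figure D3:**
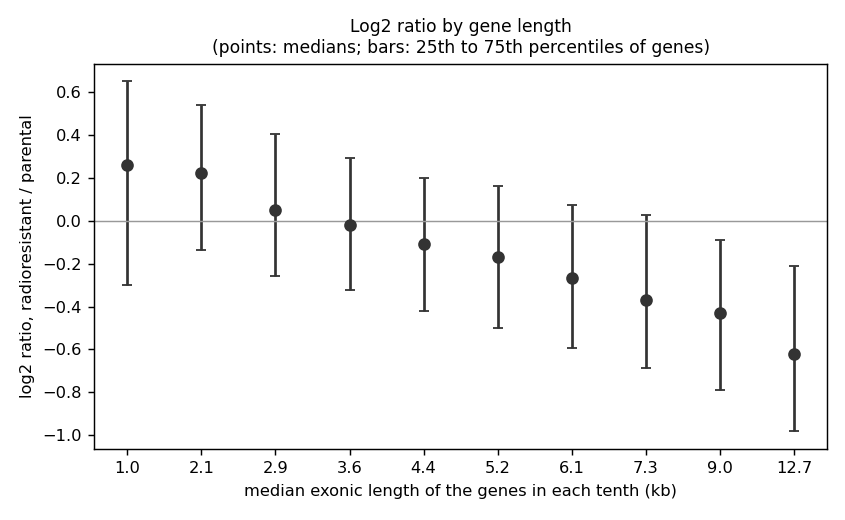
Median log2 ratio, radioresistant over parental (points), with the 25th to 75th percentiles of genes (bars), in deciles of genes by exonic length (kb). The medians go from 0.26 in the shortest to -0.62 in the longest decile.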

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

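Length matching, trend removal and the protein-coding count were chosen after the results were seen, as was one of the readings of direction described here. Counts of higher and lower genes (389 and 1036) moved by over 1.5 times in either count as follows, given as higher and lower: 530 and 1658 with a pseudocount of 0.1, 239 and 605 at a mean FPKM of at least 5, 626 and 705 at a median ratio of 0, 218 and 2227 rescaled to TPM, 209 and 2350 without mitochondrial-encoded genes, 500 and 587 after quantile normalization, 354 and 438 with trends removed, 1377 and 2963 at 1.5-fold, 74 and 76 at 4-fold, and 202 and 879 among protein-coding genes. The direction of a list was first read against the median gene. Its side of the random lists was added as a reading after results were seen, and a reversal counts under either where the list stood apart in at least one of the settings compared; 7 list or chromosome reversals appear only under the first, 4 only under the second and 2 under both. Against the median gene, glycolysis reversed with quantile normalization (-0.22) and trends removed (-0.20), hypoxia with no filter (-0.081), a mean FPKM of at least 5 (-0.081), quantile normalization (-0.20) and trends removed (-0.22), and heat shock with trends removed (-0.32). Against random lists drawn from all genes, complex III (0.29, percentile 98.0), glycolysis (-0.021, percentile 80.7) and hypoxia (-0.081, percentile 66.1) reversed, and so did chromosome 15 with length matched (-0.17). Antigen presentation with quantile normalization (-0.28) and chromosome 18 with trends removed (0.079) reversed under both, and the single gene UQCRH with trends removed (-0.37). Nuclear complex I (0.55, percentile 96.7) and glycolysis (-0.021, percentile 9.93) no longer stood apart with length matched. Complex IV came to stand apart with quantile normalization (0.36) and lists from all genes (0.57), complex V with no filter and lists from all genes (0.59 each), and interferon-stimulated genes with no filter (0.078). Abundant genes had higher ratios, so drawing lists from all genes changes the reference; the cause of the other shifts was not tested. Of 465 other list values, all on their original side of the threshold, 434 kept their direction under both readings and 31 did not, 12 of these against the median gene. The 12 were quantile normalization for the tricarboxylic acid cycle, mitochondrial biogenesis, G1/S, heat shock and housekeeping, trends removed for the tricarboxylic acid cycle, homologous recombination, G1/S, antigen presentation, myeloid markers and housekeeping, and a mean FPKM of at least 5 for neuron markers. Among the 19 main lists, 156 of 163 such values chosen in advance and 30 of 35 added ones kept both. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible either. Depth limits low genes, since an FPKM of 1 on a 2 kb transcript held 50.6 and 40.3 fragments.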

Other observations

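The effective-length test of the length trend, the comparison with random gene sets and both tests of a uniform mitochondrial loss were chosen after their results were seen, as were length matching, trend removal and the non-coding genes listed next. Of the small structured RNAs named in the text, which were no fixed list, more were higher than lower. Higher in the radioresistant library were RPPH1, the RNA of RNase P, at 1.81 FPKM in parental and 8.51 in radioresistant cells, and the signal recognition particle RNAs RN7SL1 at 82.3 and 236 and RN7SL2 at 42.7 and 143. Lower were the mitochondrial transfer RNA MT-TS1, at 5.39 and 1.54, and RNA5-8SN4, a 5.8S ribosomal RNA gene with near-identical copies, at 8.26 and listed at 0. MT-TS1, at 69 bp, is shorter than the fitted fragments and lies beside MT-CO1 on the opposite strand, so its value is uncertain. The long nuclear RNAs MALAT1 (9.27 and 4.30) and NEAT1 (9.83 and 3.34) were lower. The mitochondrial ribosomal RNAs were higher, with MT-RNR1 at 156 and 208 and MT-RNR2 at 827 and 1085, while FP236383.3 stood at 82.3 and 13.5. In all, 50 identifiers were listed at 0 in one library and at 5 FPKM or more in the other, 21 at 0 in radioresistant and 29 at 0 in parental cells, and 30 of them were shorter than 500 bp.

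By chromosome, genes on chromosomes 5 (median log2 ratio -0.25, percentile 0.16 of expression-matched lists) and 13 (-0.33, percentile 0.45) were lower than matched genes, where 1.15 of 23 chromosomes would stand apart by chance. Both stood apart with length matched, at percentiles 2.30 and 2.46, and after removal of trends chromosome 5 did (0.97) and chromosome 13 did not (20.5). With length matched chromosome 3 (98.4) and chromosome 15 (97.7) stood apart as well, and with trends removed chromosomes 4 (2.39), 11 (98.9) and 18 (97.52) did.

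The decline of log2 ratios with gene length has several technical explanations. A different effective-length calculation in each library is argued against, because the Spearman correlation stayed at -0.36 among genes longer than 2521 bp, where the fitted fragment lengths change FPKM by 0.446% at that length. Abundance in place of length is argued against by a median correlation of -0.41 within deciles of genes by mean FPKM. Loss of long RNA regardless of function, such as by RNA fragmentation or library preparation, stays open, because the test made of it decides nothing: the correlation was negative within 34 of 36 lists with at least 10 members (94.4%), and within 94.1% of random gene sets of the same sizes. A biological difference between irradiated and parental cells that acts on long genes stays open and untested, since 1 library per group cannot separate preparation from condition.

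Nuclear complex I subunits were higher and most mitochondrial-encoded mRNAs lower. Whether length, GC content and abundance trends together are the whole cause for the nuclear subunits is not decided. After removal of the fitted trends the subunits lay at percentile 99.6. Their median went from 0.69 above that of all genes (0.64 to 0.76 on resampling members) to 0.25 above it (0.04 to 0.36). The fit may leave part of the trends in place, and matching on expression and length gave a different answer for the same subunits. Gene length bias alone cannot be told apart from a difference specific to the list, because length matching, which raised the median of random lists from 0.26 to 0.38 and left that of the subunits as it was, placed them at percentile 96.7, inside the middle 95%. For the 13 mitochondrial protein-coding genes, not all of them independent members, gene length bias is argued against by percentile 0 of length-matched lists. A uniform loss of mitochondrial RNA is not decided. As measured, the 2 mitochondrial ribosomal RNAs were higher, with a median log2 ratio of 0.40. More of the named small structured RNAs were higher than lower (RN7SK 2.75 and RMRP 2.71). MT-TS1 (-1.33) was lower, but at 69 bp beside MT-CO1 its value may not be its own. Library preparation could have moved the ribosomal RNAs as well, which was not tested. The spread of the mRNA ratios, 1.93 times that of cytosolic ribosomal protein genes, did not decide it either. A loss of the mRNAs alone or of mitochondrial RNA as a whole, from library preparation or in the cells, stays open, and the radiation history was not separable from preparation.

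Immediate early genes, NF-kB targets and mitotic genes were lower as groups. Gene length bias is argued against for each of the 3, since the medians lay at percentile 0 of length-matched lists for immediate early genes, at 0 for NF-kB targets and secreted inflammatory factors, and at 0 for mitotic genes. Culture density or time since medium renewal at harvest, which growth factor-induced genes respond to, may differ between the libraries and was not tested. A lasting difference after irradiation remains a hypothesis on the same footing.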
